A study of Arabidopsis thaliana with 8 samples.

How the data were processed

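Messenger RNA was profiled by sequencing in 8 libraries from Arabidopsis thaliana seedlings of 4 genotypes, with 2 libraries per genotype: the wild type Col and plants labelled chr11/17, rlt1/2 and fha2. Each library came from total RNA of 0.05 g of seedlings at day 11, grown on plates with 16 h light and 8 h dark at 22 °C, per the labels. Samples were placed in groups by their labels alone. The labels do not say whether the libraries of a genotype came from separately grown plants, so every p-value here measures the spread between these libraries, which may be technical.

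The starting values were the expected counts per gene, that is estimated read counts that need not be whole, as deposited by the authors for each library. Beside them the authors deposited FPKM values per library and per genotype mean, recognised as such from the values because the header does not name the unit. A table of comparisons holds the authors' log2 fold changes of each mutant over Col, and the authors' p-values and q-values, per the file headers. Bowtie2, RSEM and DESeq2 and the genome build TAIR10 are named in the submitters' processing notes, with no role and no version. Whether the library kit kept strand and whether the counting used it is not given in the sources used here, so reads of overlapping genes cannot be told apart. Of the 25198 genes, 6411 (25.4%) overlap another listed gene in the reference annotation. For a named gene of this kind a fold change was also computed after adding the counts of the overlapping gene. FPKM values were not used for any test.

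Gene IDs were looked up in the NCBI RefSeq annotation of the assembly TAIR10.1, where 25198 of 25198 matched. Since this assembly and the build in the processing notes have different names, no coordinates are given, and only chromosomes and neighbouring genes were taken from it. Dates stood in place of 22 symbols in the authors' deposited files, and these genes were named from the annotation. Where 2 loci share a symbol, the locus was added to it.

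Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by genotype, which left 20866 of 25198, and scaled by TMM factors. All 8 libraries entered 1 fit with genotype as the only term, because 2 libraries per genotype leave little to estimate the spread of a pair alone. The edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was applied to 6 comparisons, each mutant against Col and each pair of mutants, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are on the log2 scale with standard errors (SE), and levels are CPM (counts scaled to library size with TMM factors), given as mean ± SD of 2 libraries. A fold against a genotype with 0 counts in both libraries is a bound, computed with 3 counts over the genotype in its place, and a genotype with 1 to 3 counts is given by the ratio of counts with its exact 95% interval. Such intervals and bounds cover counting error only.

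A set of 20 gene lists holding 305 genes was tested with camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01, for lists with at least 5 tested members, and p was adjusted over the lists of a comparison. Members were also counted by their own calls, over all genes tested and adjusted over the list alone. The lists were ISWI subunits, promoters of flowering, repressors of flowering, floral organ identity, seed maturation, shoot meristem, root markers, root hair, photosynthesis, circadian clock, salicylic acid defence, jasmonate, auxin, gibberellin, cold and abscisic acid, heat shock, anthocyanin, aliphatic glucosinolates, mitosis and iron deficiency. With a correlation estimated from the data no list was called in any comparison.

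Genes are named by a rule. It takes the 5 genes of the genotypes, the other ISWI list members, and FT, SOC1, FLC, FUL and AP1. For each mutant against Col it adds the 8 highest and the 8 lowest log2 fold changes among called genes with a symbol, at least 2 CPM in the higher genotype and no overlap between the libraries of both genotypes. For each pair of mutants it adds 4 each way, and it takes 10 genes that changed in the same direction in all 3 mutants. From each list it takes up to 4 called members with the smallest adjusted p. The groups, tests, lists, this rule and the alternatives were fixed before the data were examined. Exceptions are the omission of overlapping genes, other scalings for the lists, families and mitochondrial-like block, the counts of their called members without each library, the counts of list members with no filter, the split of the Col libraries between the mutants of a pair, and the 15 product families, which were added after seeing the data.

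Alternatives were RLE size factors, total counts, no filter on low counts, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, fits of the 2 genotypes compared alone, the replicate number as a block, each library left out in turn, and for the lists fry and an estimated correlation. When 1 library is left out, the lone library of that genotype is taken to vary like those of the other genotypes. For comparisons that share the Col libraries, 20 simulations of unchanged groups against them gave the correlation and overlap that arise with no effect. The test was tested on simulated data with counts drawn for fha2 against Col, 20104 genes tested and 200 changed: it recovered 25 of 50 genes changed by 1.5-fold, 41 of 50 at 2-fold, 48 of 50 at 4-fold and 49 of 50 at 8-fold, with 15 false calls. Further tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0, the last to find nuclear genes with at least 95% identity to the mitochondrial genome over at least 50% of their length.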

Results

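Messenger RNA was sequenced from Arabidopsis thaliana seedlings at day 11 in 8 libraries, 2 for each of 4 genotypes: the wild type Col, chr11/17, rlt1/2 and fha2. CHR11 and CHR17 are the ATPases of the plant ISWI chromatin remodelling complex, RLT1 and RLT2 are its DDT-domain subunits, and FHA2 is a forkhead-associated domain protein. The title of the series presents a plant-specific subunit of ISWI with a role in fertility and pistil growth. The comparisons asked which transcripts differed from Col in each mutant, and how far the change in fha2 resembled that in the other mutants. Total expected counts were between 20.962 M and 22.012 M per library (M, mega), so 3 counts stood for 0.136 to 0.143 CPM before TMM scaling in a single library. The 20 genes with the most counts took 22.5% and 21.4% of the counts in the Col libraries, 8.49% and 7.73% in those labelled chr11/17, 14.6% and 14.5% in rlt1/2, and 17.37% and 16.45% in fha2. In every genotype the replicates differed by more than counting noise (chi-square per degree of freedom from 4.43 to 12.9). On the first principal component, which held 74.8% of the variance, the libraries labelled chr11/17 lay at 134 and 122, those of rlt1/2 at 5.3 and -3, those of fha2 at -63.3 and -60 and those of Col at -67.7 and -67.4.

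The genes named by the genotypes were read first. FHA2 (AT3G07220), on chromosome 3, was at 24.0 ± 0.640 CPM in Col (mean ± SD, n = 2) and at 2.03 ± 1.44 in fha2, with 69 and 23 counts left in the fha2 libraries. It fell by 3.56 ± 0.255 on the log2 scale (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.85e-05). RLT2 (AT5G44180), on chromosome 5, was at 31.2 ± 4.21 CPM in Col and 2.2 ± 0.0152 in rlt1/2, and fell by 3.82 ± 0.145 (edgeR, adjusted p = 2.46e-08). RLT1 (AT1G28420), on chromosome 1, was at 30.5 ± 7.28 CPM in Col and 16.3 ± 0.685 in rlt1/2, and fell by 0.90 ± 0.169 (edgeR, adjusted p = 0.00121). RLT1 overlaps AT1G28410, so its counts are uncertain; with both loci added the log2 fold change was -0.52. RLT1 was at 45.8 ± 9.80 CPM in the libraries labelled chr11/17 and 30.3 ± 1.67 in fha2, RLT2 at 26.1 ± 1.29 and 33.1 ± 1.84, and FHA2 at 22.7 ± 0.109 in the libraries labelled chr11/17 and 21.03 ± 1.35 in rlt1/2. The labels of rlt1/2 and fha2 thus matched lower transcripts of their genes. In the libraries labelled chr11/17, neither CHR11 (AT3G06400) nor CHR17 (AT5G18620) was lower than in Col. CHR11, on chromosome 3, was at 71.6 ± 2.57 CPM against 46.8 ± 0.608 in Col and rose by 0.61 ± 0.084 (edgeR, adjusted p = 2.84e-05). CHR17, on chromosome 5, was at 22.8 ± 0.167 CPM against 19.8 ± 3.78 in Col, a log2 fold change of 0.20 ± 0.127 (edgeR, adjusted p = 0.184). It passed the test without Col replicate 2 (adjusted p = 0.0197), and its counts are uncertain because it overlaps AT5G18610. Counts over a whole gene do not show whether a transcript was interrupted, and where the mutations lie is not given in the sources used here. This genotype is therefore called the libraries labelled chr11/17, and each direction drawn from it rests on that label. CHR11 was at 49.9 ± 1.22 CPM in rlt1/2 and 44.8 ± 1.86 in fha2. CHR17 was at 20.8 ± 0.0648 CPM in fha2 and 28.5 ± 3.01 CPM in rlt1/2, where it rose by 0.52 ± 0.126 (edgeR, adjusted p = 0.00587). This call was lost without Col replicate 1 (adjusted p = 0.0611) and without rlt1/2 replicate 1 (adjusted p = 0.0671).

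**Figure D1:**
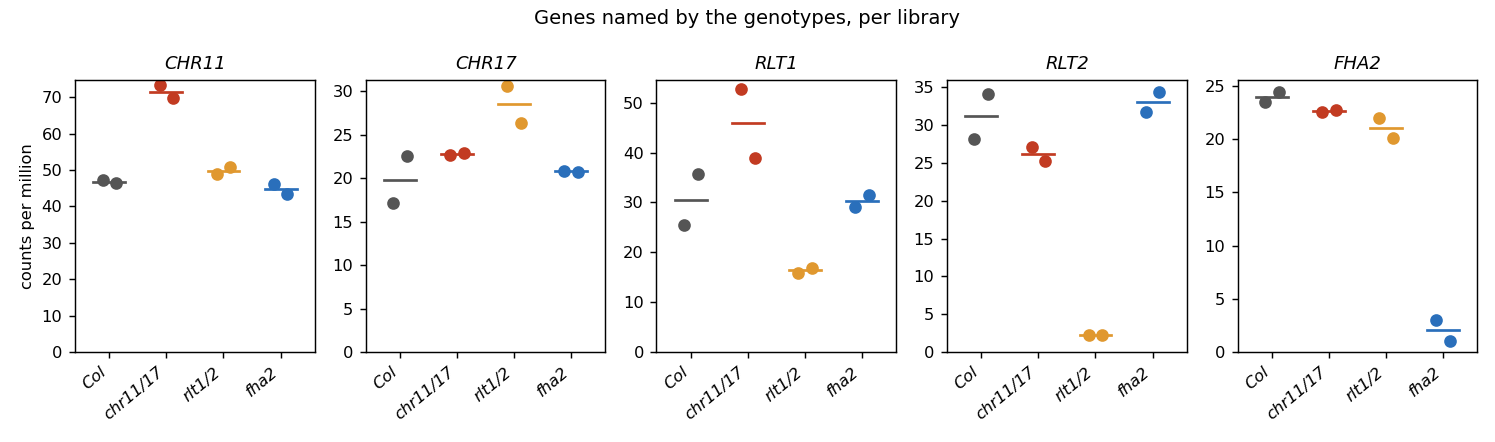
CPM (linear axis) of the 5 genes named by the genotypes in each library of the 4 genotypes. Points are libraries and short lines the means of 2; FHA2 averages 2.03 CPM in fha2 and RLT2 2.2 CPM in rlt1/2, while CHR11 averages 71.6 CPM in the libraries labelled chr11/17.

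Against Col, the libraries labelled chr11/17 had lower transcripts of photosynthesis and auxin genes and higher transcripts of jasmonate, anthocyanin, heat shock, floral organ and seed storage genes. All 22 photosynthesis genes tested fell, also adjusted over the list alone, with a median log2 fold change of -2.26 (camera adjusted p = 2.93e-12, adjusted p = 0.353 with an estimated correlation). The light-harvesting gene LHB1B1 (AT2G34430) dropped from 3615 ± 126 CPM to 108 ± 25.2, a log2 fold change of -5.06 ± 0.170. The Rubisco small subunit genes RBCS2B (AT5G38420) and RBCS3B (AT5G38410) fell by 3.49 ± 0.133 and 3.84 ± 0.150. These are near-identical copies, so the split of reads between them is uncertain. Of the 27 auxin genes 23 fell and 2 rose, also adjusted over the list alone (median -2.44, camera adjusted p = 9.40e-06, adjusted p = 0.378 with an estimated correlation). IAA7 (AT3G23050), a repressor of auxin response, dropped from 162 ± 14.2 to 21.8 ± 1.17 CPM, and the early auxin response genes SAUR20 (AT5G18020) and SAUR23 (AT5G18060) fell by 5.95 ± 0.201 and 6.83 ± 0.297.

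Jasmonate genes rose in 18 of 21 cases and 1 fell, also adjusted over the list alone (median 2.01, camera adjusted p = 9.40e-06, adjusted p = 0.353 with an estimated correlation). JAZ10 (AT5G13220), a repressor of jasmonate signalling that the hormone itself induces, went from 1.91 ± 0.460 to 39.3 ± 1.28 CPM, JAZ1 (AT1G19180) rose by 2.48 ± 0.104, and LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, by 3.89 ± 0.193. Of 15 anthocyanin genes 12 rose and none of the others passed the test, with the same counts adjusted over the list alone, though 2 were lower without Col replicate 2 and 1 without chr11/17 replicate 2 (median 2.85, camera adjusted p = 9.40e-06, adjusted p = 0.353 with an estimated correlation). The flavonoid hydroxylase gene TT7 (AT5G07990) was at 114 ± 1.54 CPM against 12.2 ± 1.04, and the glycosyltransferase gene UF3GT (AT5G54060) rose by 3.64 ± 0.172. Heat shock genes rose in 9 of 11 cases, and adjusted over the list alone 9 rose and 1 fell (median 2.91, camera adjusted p = 0.00518, adjusted p = 0.353 with an estimated correlation). HSP90.1 (AT5G52640) rose by 2.73 ± 0.114 and the small heat shock protein gene HSP18.2 (AT5G59720) by 3.48 ± 0.198. Iron deficiency genes fell in 9 of 12 cases and rose in 1, also adjusted over the list alone (median -2.76, camera adjusted p = 0.00848, adjusted p = 0.423 with an estimated correlation). BHLH100 (AT2G41240), a transcription factor induced by lack of iron, was 406-fold lower by counts (95% exact interval 72.4 to 16100), and BTS (AT3G18290), an E3 ligase of the iron response, fell by 1.55 ± 0.108.

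Genes of flowers and seeds rose in these seedlings. Of 10 floral organ identity genes tested 8 rose and 1 fell, also adjusted over the list alone, or 7 and 1 of 12 with no filter on low counts (median 4.44, camera adjusted p = 0.0125, adjusted p = 0.353 with an estimated correlation). AP3 (AT3G54340), which specifies petals and stamens, went from 0.324 ± 0.0701 to 40.4 ± 0.849 CPM, a log2 fold change of 6.94 ± 0.223, and SEP3 (AT1G24260), a cofactor of floral organ identity, from 5.12 ± 1.89 to 233 ± 46.5 CPM. All 10 seed maturation genes tested rose, also adjusted over the list alone, with a median of 7.49, or 6.64 with genes at 0 counts in Col set to their bounds (camera adjusted p = 0.0125, adjusted p = 0.538 with an estimated correlation). The other 5 of the 15 listed genes, with at most 19 counts in a library, were removed by the filter on low counts, which keeps genes near 0 in Col where a mutant expresses them, and with no filter 10 of 15 rose and 0 fell (median 6.34). The cruciferin gene CRU3 (AT4G28520), a seed storage protein, was at 103 ± 63.4 CPM with 0 counts in Col, at least 1249-fold higher, and the cruciferin gene CRA1 (AT5G44120) went from 0.429 ± 0.374 to 158 ± 82.3 CPM. Of 8 shoot meristem genes 5 rose and none fell, also adjusted over the list alone (median 1.68, camera adjusted p = 0.0389, adjusted p = 0.353 with an estimated correlation). The boundary gene CUC1 (AT3G15170) rose by 4.44 ± 0.447 and the meristem gene STM (AT1G62360) by 3.07 ± 0.365.

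Among the flowering genes, FLC (AT5G10140), a repressor of flowering, had 66 and 84 counts in Col and 0 and 1 in the libraries labelled chr11/17, 185-fold lower (95% exact interval 32.6 to 7342; edgeR, adjusted p = 2.15e-07). The repressor SVP (AT2G22540) dropped from 78.9 ± 3.38 to 14.1 ± 0.428 CPM. As a list the repressors of flowering had 8 members lower and 2 higher of 14 (7 and 5 with total counts) but were not called (camera adjusted p = 0.12). FT (AT1G65480), the mobile inducer of flowering, was at 0.703 ± 0.0322 CPM against 0.245 ± 0.196 and rose by 1.51 ± 0.545 (edgeR, adjusted p = 0.026). This call was lost without Col replicate 2 (adjusted p = 0.202), chr11/17 replicate 1 (0.0694) or chr11/17 replicate 2 (0.0537). AGL20 (AT2G45660), also called SOC1, had a log2 fold change of -0.41 ± 0.188 (edgeR, adjusted p = 0.0687), which passed the test without chr11/17 replicate 1 (adjusted p = 0.00311). AGL8 (AT5G60910), also called FUL, had one of -0.41 ± 0.383 (edgeR, adjusted p = 0.36). AP1 (AT1G69120), a floral meristem gene, had 7.31 times the counts of Col (95% exact interval 1.75 to 65.0; edgeR, adjusted p = 0.0426), a call lost without Col replicate 2 (0.226) or chr11/17 replicate 1 (0.495). In the ISWI list 5 of 11 members rose and 1 fell, 8 and 1 with total counts (camera adjusted p = 0.292). The histone-binding genes MSI1 (AT5G58230), MSI2 (AT2G16780) and MSI3 (AT4G35050) rose by 0.75 ± 0.095, 0.90 ± 0.112 and 1.21 ± 0.120, and PTM (AT5G35210) fell by 0.90 ± 0.099. RLT1 rose by 0.58 ± 0.159 (edgeR, adjusted p = 0.00561), a call lost without Col replicate 1 (0.0808) or chr11/17 replicate 1 (0.0676). RLT3 (AT4G12750) (0.45 ± 0.240) and ARID5 (AT3G43240) (0.05 ± 0.114) did not pass. The 3 MSI genes and ARID5 overlap neighbours, so their counts are uncertain.

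The highest named genes besides CRU3 were DXPS1 (AT3G21500) (at least 1081-fold higher), CSLG2 (AT4G24000), a cellulose synthase-like gene (at least 525-fold), and a cytochrome P450 gene, CYP82G1 (AT3G25180) (at least 139-fold). Of the seed albumin genes, SESA3 (AT4G27160) was at least 92.3-fold higher and SESA1 (AT4G27140), with few counts in Col, 1557-fold higher by counts (exact interval 279 to 61530). MYC2 (AT1G32640) and RLP40 (AT3G24982) had 0 counts in Col (at least 118-fold and 112-fold higher), but each overlaps a neighbour, and with both loci added the log2 fold changes were 1.24 and 4.0. DXPS1 also has an overlapping neighbour. Lowest were RGF6 (AT4G16515), a root growth factor peptide gene (at least 392-fold lower, with an overlapping neighbour and a log2 fold change of -1.17 with both loci added), SAUR22 (AT5G18050) (at least 214-fold) and IAA6 (AT1G52830) (at least 58.3-fold). Next came ACS4 (AT2G22810), an ethylene synthesis gene (at least 43.5-fold), PRB1 (AT2G14580) (at least 34.5-fold), BHLH100, PAP14 (AT2G46880) (309-fold, interval 105 to 1502) and PCC1 (AT3G22231) (294-fold, interval 81.0 to 2437).

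In all, 7255 genes were higher and 7171 lower in the libraries labelled chr11/17 than in Col, 69.1% of the 20866 tested, and of these 3434 and 3737 changed by at least 2-fold. Lists not called were clock (2 higher and 7 lower of 15, camera adjusted p = 0.293), cold and abscisic acid (7 and 4 of 13, 0.349), and aliphatic glucosinolates (5 and 1 of 13, 0.33). Also not called were promoters of flowering (3 and 3 of 10, camera adjusted p = 0.698), gibberellin (7 and 7 of 18, 0.812), mitosis (3 and 7 of 18, 0.536) and root markers (2 and 3 of 11, 0.536). Root hair genes had 0 higher and 5 lower of 8, or 4 lower adjusted over the list alone (camera adjusted p = 0.293). Salicylic acid defence had 7 higher and 5 lower of 18 (camera adjusted p = 0.812), and its median of -0.08 lay opposite to its mean of 0.22 and its test. Called members became 4 lower for mitosis without Col replicate 2 or chr11/17 replicate 2, 1 higher for promoters of flowering without chr11/17 replicate 1 and 4 higher for gibberellin without Col replicate 2. They became 3 lower for root hair without Col replicate 1, and 5 lower for root markers without Col replicate 2 or chr11/17 replicate 2. Lower aliphatic glucosinolate genes became 3 without chr11/17 replicate 1 (median -0.11, against 0.21 with all libraries) and 2 without Col replicate 2 (-0.03). Medians also changed sign for gibberellin without Col replicate 2 (0.18), for root markers without chr11/17 replicate 1 (-0.46 to 0.04) and for salicylic acid defence without Col replicate 1 (0.50) or chr11/17 replicate 1 (0.10). Counts of 0 to 2 members moved by 1 without some library for iron deficiency, the ISWI list, jasmonate, root hair and root markers. Among them PRR7 (AT5G02810), a clock repressor, fell by 2.12 ± 0.102, CYCB1;1 (AT4G37490), a mitotic cyclin gene, rose by 2.15 ± 0.148, and GID1B (AT3G63010), a gibberellin receptor gene, by 2.02 ± 0.145. BGL2 (AT3G57260), a glucanase of defence, rose by 2.56 ± 0.242 and LTI65 (AT5G52300) by 3.75 ± 0.291, while LRX1 (AT1G12040) of root hairs fell by 1.54 ± 0.166. Scaling by total counts instead of TMM raised the median log2 fold change of all genes by 0.27 here, 0.29 in rlt1/2 and 0.26 in fha2, and gave 9243 higher and 5227 lower genes. It moved the higher and lower members to 5 and 6 for clock, 6 and 4 for mitosis, 1 and 3 for root hair, 3 and 3 for root markers and 8 and 1 for aliphatic glucosinolates. It also turned the medians of clock (-0.22 to 0.07), gibberellin (-0.08 to 0.19) and salicylic acid defence (-0.08 to 0.20). List calls ended without Col replicate 2 for floral organ and seed maturation genes (both adjusted p = 0.0506), and without overlapping genes for floral organ (0.0593) and iron deficiency genes (0.0523). For shoot meristem genes the adjusted p was 0.0711 and 0.0919 without Col replicate 1 or 2, 0.0675 and 0.0752 without chr11/17 replicate 1 or 2, and 0.0571 with total counts.

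**Figure D2:**
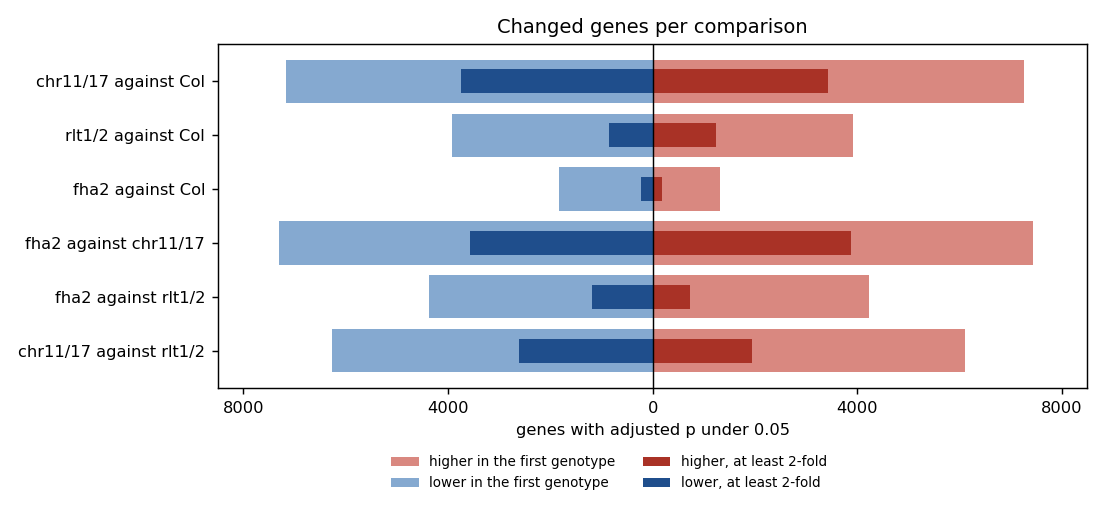
Number of genes with an edgeR adjusted p under 0.05 in each of the 6 comparisons (horizontal axis, bars from 0), higher to the right and lower to the left. Narrow dark bars are genes changed by at least 2-fold; fha2 against Col has 1320 higher and 1828 lower genes, against 7255 and 7171 for the libraries labelled chr11/17.

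In rlt1/2 against Col, seed storage, floral organ, anthocyanin and heat shock genes were higher and photosynthesis, auxin and iron deficiency genes lower. CRU3 was at 36.7 ± 3.71 CPM with 0 counts in Col, at least 453-fold higher, and CRA1 at 50.2 ± 5.84 against 0.429 ± 0.374 CPM, a log2 fold change of 6.84 ± 0.505 (edgeR, adjusted p = 1.32e-06). AP3 rose by 5.20 ± 0.253 to 12.1 ± 1.49 CPM and SEP3 by 4.63 ± 0.305 to 128 ± 1.77 CPM. FLC, with 2 counts in each library, fell by 5.45 ± 0.463 (edgeR, adjusted p = 3.72e-06), and FT rose by 3.12 ± 0.469 to 2.16 ± 0.0155 CPM (adjusted p = 2.67e-04).

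All 22 photosynthesis genes fell, also adjusted over the list alone (median -0.88, camera adjusted p = 8.90e-12, adjusted p = 0.282 with an estimated correlation). LHB1B1 was at 1255 ± 23 CPM and a log2 fold change of -1.53 ± 0.146, and RBCS2B fell by 1.52 ± 0.123. Anthocyanin genes rose in 12 of 15 cases and fell in 1, also adjusted over the list alone (median 1.71, camera adjusted p = 1.67e-08, adjusted p = 0.282 with an estimated correlation). DFR (AT5G42800), dihydroflavonol reductase, rose by 2.12 ± 0.155 and UF3GT by 2.33 ± 0.175. Heat shock genes rose in 8 of 11 cases, or 10 adjusted over the list alone (median 2.27, camera adjusted p = 3.94e-06, adjusted p = 0.141 with an estimated correlation). HSP90.1 rose by 2.41 ± 0.115 and HSFA2 (AT2G26150), a heat shock transcription factor, by 5.01 ± 0.311. Auxin genes fell in 17 of 27 cases and rose in 3, also adjusted over the list alone (median -1.04, camera adjusted p = 1.25e-05, adjusted p = 0.398 with an estimated correlation). IAA29 (AT4G32280) fell by 3.21 ± 0.212 and SAUR20 by 1.58 ± 0.127. Iron deficiency genes fell in 9 of 12 cases, or 10 adjusted over the list alone (median -1.33, camera adjusted p = 4.07e-05, adjusted p = 0.361 with an estimated correlation). BHLH100 fell by 4.49 ± 0.357 and BTS by 1.18 ± 0.106.

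Floral organ genes rose in 5 of 10 cases, 6 adjusted over the list alone, and none fell (median 2.81, camera adjusted p = 0.00354, adjusted p = 0.206 with an estimated correlation). Seed maturation genes rose in 8 of 10 cases, also adjusted over the list alone, or 9 of 15 with no filter (median 6.05, 5.16 with no filter, 5.21 with genes at 0 counts in Col set to their bounds, camera adjusted p = 0.00709, adjusted p = 0.508 with an estimated correlation). Repressors of flowering fell in 9 of 14 cases and rose in 2, with 10 lower and 2 higher adjusted over the list alone and 6 and 3 with total counts (median -0.60, camera adjusted p = 0.0012, adjusted p = 0.192 with an estimated correlation). Besides FLC, SNZ (AT2G39250) fell by 2.55 ± 0.165, MAF3 (AT5G65060) by 2.50 ± 0.187 and SVP by 0.61 ± 0.082. Aliphatic glucosinolate genes rose in 7 of 13 cases and fell in 1, with 10 and 1 adjusted over the list alone (median 0.49, camera adjusted p = 0.00354, adjusted p = 0.508 with an estimated correlation). The 7 became 4 without Col replicate 2, and 11 with total counts. The sulfotransferase gene SOT17 (AT1G18590) rose by 0.85 ± 0.133 and the cytochrome P450 gene CYP83A1 (AT4G13770) by 0.81 ± 0.153. Mitosis genes rose in 5 of 18 cases and none fell, also adjusted over the list alone (median 0.35, camera adjusted p = 0.00844, adjusted p = 0.5 with an estimated correlation). The 5 became 3 without Col replicate 1, Col replicate 2 or rlt1/2 replicate 1, and 12 with total counts. CDC20.1 (AT4G33270), a regulator of mitotic exit, rose by 0.52 ± 0.112. Jasmonate genes rose in 8 of 21 cases and fell in 2, also adjusted over the list alone, or 11 and 1 with total counts (median 0.39, camera adjusted p = 0.0192, adjusted p = 0.508 with an estimated correlation). JAZ7 (AT2G34600) rose by 3.67 ± 0.293 and JAZ1 by 1.09 ± 0.105.

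Further named genes were OLEO1 (AT4G25140), an oleosin (229-fold higher by counts, exact interval 40.8 to 9078), SESA1 (200-fold, interval 35.6 to 7931), and SESA3 (at least 28.8-fold). Others were TIP3;1 (AT1G73190) (174-fold, interval 30.9 to 6912), DELTA-VPE (AT3G20210), a vacuolar protease gene (90.7-fold, interval 24.8 to 754), and emb1796 (AT3G49240) (at least 40.6-fold). OLEO1, TIP3;1 and emb1796 overlap neighbours, and with both loci added their log2 fold changes were 1.41, 0.14 and 0.35. Lowest were BHLH101 (AT5G04150) (78.9-fold, interval 26.6 to 386) and bHLH38 (AT3G56970) (-5.74 ± 0.282), both of the iron response and both overlapping a neighbour (-0.89 and -2.47 with both loci added). Next came FLC, ACS4 (-4.64 ± 0.546), BHLH100, MRD1 (AT1G53480) (-4.33 ± 0.253, with an overlapping neighbour) and RLT2. GASA6 (AT1G74670), a gibberellin-regulated peptide gene, dropped from 543 ± 36.4 to 38.9 ± 3.42 CPM. AGL20 (SOC1) fell by 1.01 ± 0.195 (edgeR, adjusted p = 0.00151) and AGL8 (FUL) had 0.30 ± 0.357 (adjusted p = 0.547). AP1 had 7.66 times the counts of Col (exact interval 1.85 to 67.8; edgeR, adjusted p = 0.0632). In the ISWI list 5 of 11 members rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.832), with a median of 0.19 and a mean of -0.27, and 6 rose and 2 fell with total counts. The 5 became 1 without Col replicate 1, 3 without Col replicate 2 or rlt1/2 replicate 1 and 2 without rlt1/2 replicate 2. PTM fell by 0.41 ± 0.096 and MSI2 rose by 0.49 ± 0.114.

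In all, 3912 genes were higher and 3912 lower in rlt1/2 than in Col, 37.5% of those tested, and 1244 and 856 changed by at least 2-fold; with total counts 8108 were higher and 1849 lower. The clock list (3 higher and 7 lower of 15, camera adjusted p = 0.113) was not called, nor were cold and abscisic acid (2 and 5 of 13, 0.0742), promoters of flowering (1 and 2 of 10, 0.619) and gibberellin (3 and 4 of 18, 0.814). The same held for root hair (2 and 0 of 8, camera adjusted p = 0.0904), root markers (2 and 1 of 11, 0.443), salicylic acid defence (8 and 3 of 18, or 10 and 4 adjusted over the list alone, 0.0762) and shoot meristem (2 and 2 of 8, 0.619). Lower clock genes became 4 without Col replicate 1 and 3 without rlt1/2 replicate 1, and lower gibberellin genes 2 without rlt1/2 replicate 1. Higher defence genes became 4 without Col replicate 2 and 5 without any 1 of the other libraries of Col and rlt1/2, and lower ones 1 without Col replicate 1 or rlt1/2 replicate 1. Shoot meristem had 3 higher and 1 lower without Col replicate 1, 0 and 0 without Col replicate 2, 1 and 1 without rlt1/2 replicate 1 and 1 and 0 without rlt1/2 replicate 2. Higher root hair genes became 5 without Col replicate 1 and 1 without any 1 of the other libraries, and lower jasmonate genes 0 without rlt1/2 replicate 1 or 2. Counts of 1 or 2 members moved by 1 without some library for anthocyanin, cold and abscisic acid, jasmonate, promoters and repressors of flowering and root markers, and the gibberellin median was 0.01 without Col replicate 1. With total counts the higher and lower members became 3 and 3 for clock, 4 and 4 for cold and abscisic acid (1 and 5 with RLE size factors), 4 and 2 for promoters of flowering and 7 and 2 for gibberellin. Root hair had 6 and 0, root markers 4 and 0, salicylic acid defence 11 and 2 and shoot meristem 4 and 0. The medians of clock (-0.21 to 0.07) and gibberellin (-0.13 to 0.16) changed sign there. Among the members of these lists PRR7 fell by 0.87 ± 0.095, KIN1 (AT5G15960), a cold-induced gene, by 2.16 ± 0.129 and GAI (AT1G14920), a DELLA repressor of gibberellin response, by 0.66 ± 0.088, while BGL2 rose by 2.48 ± 0.242. List calls ended without Col replicate 2 for jasmonate (adjusted p = 0.189), without overlapping genes for mitosis (0.105), with total counts for floral organ (0.0603), jasmonate (0.0862) and seed maturation (0.092). Under fry, which does not compare a list with other genes, they ended for aliphatic glucosinolates (adjusted p = 0.0633), jasmonate (0.0732) and seed maturation (0.116).

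The comparison of fha2 with Col showed smaller changes, led by lower photosynthesis genes and higher anthocyanin genes. Of 22 photosynthesis genes 18 fell, or 21 adjusted over the list alone (median -0.63, camera adjusted p = 4.77e-13, adjusted p = 0.342 with an estimated correlation). The 18 became 8 without Col replicate 1 or fha2 replicate 1 and 3 without fha2 replicate 2. LHB1B1 was at 1854 ± 197 CPM against 3615 ± 126 in Col, a log2 fold change of -0.96 ± 0.144, and RBCS1B (AT5G38430), with near-identical copies and so an uncertain share of reads, fell by 1.04 ± 0.127. Of 15 anthocyanin genes 12 rose, and adjusted over the list alone 12 rose and 1 fell (median 1.45, camera adjusted p = 2.71e-11, adjusted p = 0.342 with an estimated correlation). DFR went from 32.0 ± 4.80 to 103 ± 14.7 CPM, LDOX (AT4G22880), anthocyanidin synthase, rose by 1.65 ± 0.164. The anthocyanin acyltransferase gene AT5MAT (AT3G29590) rose by 1.80 ± 0.145 and PAP1_AT1G56650, a MYB activator of the pathway, by 1.92 ± 0.289. Auxin genes fell in 12 of 27 cases, or 13 with 1 higher adjusted over the list alone (median -0.38, camera adjusted p = 6.09e-04, adjusted p = 0.766 with an estimated correlation). The 12 became 4 without Col replicate 2 or fha2 replicate 2 and 5 without fha2 replicate 1, and with total counts 7 were lower and 4 higher (median -0.13). SAUR20 fell by 1.2 ± 0.124 and IAA29 by 1.35 ± 0.181.

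FLC had 15 counts in each fha2 library and fell by 2.61 ± 0.330 (edgeR, adjusted p = 7.81e-04), from 4.05 ± 0.609 to 0.660 ± 0.00305 CPM. MAF5 (AT5G65080), a relative of FLC, fell by 2.24 ± 0.318 (adjusted p = 0.00161). As a list the repressors of flowering had 4 of 14 members lower, or 5 with 1 higher adjusted over the list alone, and were not called (camera adjusted p = 0.066). Without Col replicate 2 or fha2 replicate 2, 2 were lower, and with total counts 3 were lower and 3 higher, while the median went from -0.14 to 0.11. FT (-0.64 ± 0.718, edgeR, adjusted p = 0.58), AGL20 (0.41 ± 0.182, 0.149), AGL8 (-0.12 ± 0.372, 0.856) and AP1 (2.04 times the counts of Col, exact interval 0.333 to 21.4, 0.692) did not pass the test. Heat shock genes rose in 3 of 11 cases, or 4 adjusted over the list alone (median 0.41, camera adjusted p = 0.0161, adjusted p = 0.342 with an estimated correlation). Of the 3 calls 0 were left without Col replicate 1 or fha2 replicate 2 and 1 without Col replicate 2 or fha2 replicate 1, while total counts gave 6. HSP18.2 rose by 1.1 ± 0.224, a call lost without Col replicate 1 (edgeR, adjusted p = 0.0539) or fha2 replicate 2 (0.0887). Mitosis genes rose in 4 of 18 cases, or 5 with 1 lower adjusted over the list alone (median 0.33, camera adjusted p = 0.00753, adjusted p = 0.75 with an estimated correlation). Of the 4 calls 2 were left without Col replicate 1, 1 without Col replicate 2 and 0 without fha2 replicate 1 or 2, while total counts gave 10. HIK (AT1G18370), a kinesin of cell division, rose by 0.62 ± 0.126, a call lost without Col replicate 2 (edgeR, adjusted p = 0.0524), fha2 replicate 1 (0.0668) or fha2 replicate 2 (0.0616). In the ISWI list the called member was FHA2 itself, 4 members were higher and 1 lower with total counts, and the camera adjusted p was 0.881 (median 0.07, mean -0.23).

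The highest named genes were MYC2 (0 counts in Col, at least 40.7-fold higher, with an overlapping neighbour and a log2 fold change of 0.41 with both loci added) and LTI65, a gene of the abscisic acid response (2.87 ± 0.309). They were followed by BAM5 (AT4G15210), a beta-amylase (2.47 ± 0.185), DIN2 (AT3G60140), a beta-glucosidase gene induced in the dark (2.15 ± 0.264), PAP1_AT1G56650 and AT5MAT. Next were NF-YA10 (AT5G06510), a subunit of the NF-Y transcription factor (1.76 ± 0.291), and UGT75C1 (AT4G14090), an anthocyanin glucosyltransferase (1.74 ± 0.182, with an overlapping neighbour). Lowest were NRPE3B (AT2G15400), an RNA polymerase subunit gene (-4.15 ± 0.364), FHA2, FLC and the cineole synthase copy TPS-CIN_AT3G25830 (-2.46 ± 0.411). They were followed by TCL1 (AT2G30432), a MYB repressor of trichome formation (-2.43 ± 0.451; lost without fha2 replicate 2, edgeR adjusted p = 0.079), and MAF5. Next were DIR1 (AT5G48485), a lipid transfer protein (-2.08 ± 0.326, or -0.65 with an overlapping neighbour added), and the cineole synthase copy TPS-CIN_AT3G25820 (-1.91 ± 0.407). The cineole synthase copies are near-identical, so the split of reads between them is uncertain, and the second call was lost without Col replicate 1 (adjusted p = 0.0524) or fha2 replicate 2 (0.0554).

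In all, 1320 genes were higher and 1828 lower in fha2 than in Col, 15.1% of those tested, and 190 and 220 changed by at least 2-fold; 6477 had an unadjusted p under 0.05. Lists not called were aliphatic glucosinolates (1 higher and 0 lower of 13, camera adjusted p = 0.192), clock (0 and 2 of 15, 0.772) and gibberellin (1 and 0 of 18, 0.474). Cold and abscisic acid genes had 3 higher and 0 lower of 13, with 1 lower adjusted over the list alone (camera adjusted p = 0.0691). Floral organ genes had 1 higher and 2 lower of 10 (camera adjusted p = 0.93), with a median of -0.28 and a mean of 0.07. No call was made for iron deficiency (0 and 1 of 12, camera adjusted p = 0.282), jasmonate (4 and 0 of 21, 0.0738), root hair (0 and 2 of 8, 3 lower adjusted over the list alone, 0.101) and salicylic acid defence (1 and 0 of 18, 0 and 0 adjusted over the list alone, 0.199). Higher jasmonate genes became 1 without Col replicate 2 or fha2 replicate 2 and 2 without fha2 replicate 1. Floral organ had 0 higher and 0 lower without Col replicate 1 or fha2 replicate 2, 1 and 0 without Col replicate 2 and 1 and 1 without fha2 replicate 1. Lower clock genes became 1 without Col replicate 2 and 0 without fha2 replicate 1 or 2, and lower root hair genes 4 without Col replicate 2 and 0 without any 1 of the other libraries. The aliphatic glucosinolate call became 2 without Col replicate 1 and 0 without Col replicate 2 (median -0.02, against 0.13 with all libraries) or either fha2 library. The salicylic acid defence call was lost without each of these 3 libraries, the gibberellin call without fha2 replicate 2 and the iron deficiency call without any 1 library. Of root markers 2 were lower without Col replicate 2 (median 0.11; 0.04 without fha2 replicate 2), and the ISWI median was -0.04 without Col replicate 1. No member was called by edgeR among promoters of flowering (10 genes, camera adjusted p = 0.772), root markers (11, 0.851), seed maturation (10, 0.881) and shoot meristem (8, 0.686). In these lists 3, 4, 0 and 1 members had an unadjusted p under 0.05, and DESeq2 called 0 in each. The number of changed genes was 1736 without Col replicate 1, 1304 without Col replicate 2, 1220 without fha2 replicate 1 and 444 without fha2 replicate 2, against 3148 with all libraries. With total counts cold and abscisic acid (7 higher and 0 lower, median 0.37, camera adjusted p = 0.0449) and root hair (0 and 0, -0.10, 0.0327) became called as lists. Other members were then 3 and 1 for clock (median -0.08 to 0.17), 1 and 0 for iron deficiency (-0.08 to 0.17), 2 and 0 for root markers (-0.10 to 0.14) and 2 and 1 for floral organ. Jasmonate had 8 and 0, salicylic acid defence 6 and 0, aliphatic glucosinolates 5 and 0, and promoters of flowering, gibberellin and shoot meristem 2 and 0 each. Of all genes 6059 were then higher and 665 lower, and DESeq2 called 814 higher and 1683 lower. List calls ended without fha2 replicate 1 for mitosis (adjusted p = 0.0991), with total counts for heat shock (0.151), and under fry for auxin (0.104) and mitosis (0.097).

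**Figure D3:**
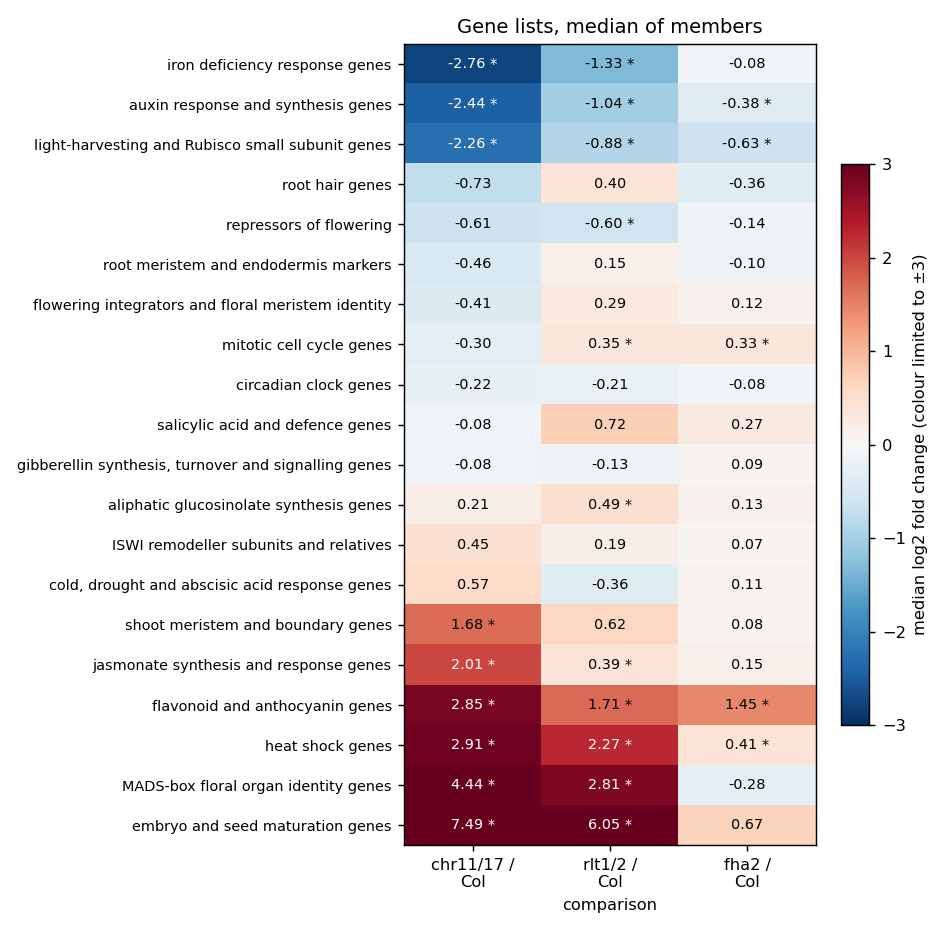
Median log2 fold change of the tested members of the 20 gene lists (vertical axis) in each mutant against Col (horizontal axis), coloured from blue for lower to red for higher, where an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Photosynthesis has medians of -2.26, -0.88 and -0.63 and anthocyanin 2.85, 1.71 and 1.45.

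Between fha2 and the libraries labelled chr11/17, seed storage, floral organ and jasmonate genes were lower in fha2 and photosynthesis, auxin and iron deficiency genes higher. CRU3 was 4601-fold lower in fha2 by counts (exact interval 825 to 181800) and AP3 fell by 7.35 ± 0.223 (edgeR, adjusted p = 1.89e-10). LHB1B1 was higher in fha2 by 4.1 ± 0.162, IAA7 by 2.42 ± 0.101 and FLC 30.1-fold by counts (exact interval 5.0 to 1228; edgeR, adjusted p = 1.57e-04). FT fell by 2.15 ± 0.567 (edgeR, adjusted p = 0.00443) and AGL20 rose by 0.82 ± 0.183, whereas AGL8 (0.28 ± 0.376) and AP1 (-1.80 ± 0.909) did not pass. AP1 passed without chr11/17 replicate 2 (edgeR, adjusted p = 0.0146). FHA2 fell by 3.48 ± 0.254 and CHR11 by 0.67 ± 0.083. The other named extremes were BSMT1 (AT3G11480) (at least 245-fold lower in fha2), THI2.1 (AT1G72260), a thionin (at least 196-fold), and CYP82G1 (at least 171-fold), and on the other side RGF6 (at least 156-fold higher), SAUR22 (at least 107-fold), PRB1 (at least 58.8-fold) and BHLH100 (278-fold, exact interval 49.5 to 11010). BSMT1, THI2.1 and RGF6 overlap neighbours, with log2 fold changes of -0.71, -1.07 and 0.25 when both loci are added. Photosynthesis genes were higher in fha2 (22 of 22, median 1.62, camera adjusted p = 9.01e-10), as were auxin (22 higher and 2 lower of 27, 3 lower adjusted over the list alone, 2.28, 4.62e-05) and iron deficiency genes (10 and 1 of 12, 2 lower adjusted over the list alone, 2.47, 0.0111). The adjusted p of these lists was 0.485, 0.492 and 0.492 with an estimated correlation. Lower lists were jasmonate (1 higher and 17 lower of 21, 18 lower adjusted over the list alone, median -1.69, camera adjusted p = 4.62e-05), anthocyanin (1 and 12 of 15, -1.33, 3.72e-04) and floral organ (0 and 8 of 10, -3.84, 0.00617). So were heat shock (2 and 8 of 11, 9 lower adjusted over the list alone, median -2.32, camera adjusted p = 0.0111) and seed maturation (0 and 10 of 10, or of 15 with no filter, -6.58, 0.0111). The adjusted p of these 5 was 0.485, 0.492, 0.442, 0.442 and 0.533 with an estimated correlation. The median and the test differed in sign from the mean, or from each other, for gibberellin (median -0.05, mean 0.67, tested higher) and cold and abscisic acid (median -0.22, mean 0.12, tested lower), neither called. In all, 7431 genes were higher and 7311 lower in fha2, 3870 and 3571 by at least 2-fold. The iron deficiency call ended without overlapping genes (adjusted p = 0.0624), and directions rest on the label chr11/17. Without chr11/17 replicate 1 the medians of cold and abscisic acid and gibberellin were 0.21 and 0.03, and the latter 0.04 without fha2 replicate 2. Counts of 0 to 2 members moved by 1 without some library for anthocyanin, floral organ, heat shock and jasmonate.

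Between fha2 and rlt1/2, floral organ, seed maturation and heat shock genes were lower in fha2, and iron deficiency, cold and abscisic acid and flowering repressor genes higher. SEP3 fell by 3.17 ± 0.266 (edgeR, adjusted p = 5.28e-06), HSP90.1 by 2.00 ± 0.108 and FT by 3.76 ± 0.486 (adjusted p = 1.1e-04). KIN1 rose by 1.80 ± 0.129, FLC by 2.84 ± 0.595 (adjusted p = 0.00251) and AGL20 by 1.42 ± 0.190. AGL8 (-0.42 ± 0.350) and AP1 (-1.86 ± 0.901) did not pass. RLT2 rose by 3.91 ± 0.143 and FHA2 fell by 3.37 ± 0.255. The lowest named genes were CRU3 (1667-fold lower by counts, exact interval 299 to 65890), UKL5 (AT3G27440) (127-fold, interval 43.3 to 620), TIP3;1 (107-fold, interval 29.2 to 888) and CRA1 (-6.56 ± 0.469). The highest were BHLH101 (76.4-fold, interval 25.8 to 373), bHLH38 (5.02 ± 0.295), BHLH100 (3.94 ± 0.366) and RLT2. UKL5, TIP3;1, BHLH101 and bHLH38 overlap neighbours, with -0.49, -0.17, 0.77 and 1.69 when both loci are added. Lower lists in fha2 were heat shock (0 higher and 7 lower of 11, median -1.24, camera adjusted p = 1.75e-04), floral organ (0 and 6 of 10, -2.69, 9.23e-04) and seed maturation (0 and 8 of 10, -5.06, or -2.96 over 15 genes with no filter, 0.00712). Root hair (0 and 6 of 8, median -0.87, camera adjusted p = 0.00764), anthocyanin (1 and 9 of 15, -0.43, 0.0169) and aliphatic glucosinolates (1 and 6 of 13, -0.27, 0.0293) were lower too. These counts were the same adjusted over the list alone, and the adjusted p of the 6 lists was 0.164, 0.164, 0.574, 0.574, 0.623 and 0.643 with an estimated correlation. Higher lists were iron deficiency (9 and 0 of 12, median 0.87, camera adjusted p = 1.75e-04), cold and abscisic acid (8 and 0 of 13, 1.01, 0.00348) and auxin (16 and 3 of 27, 0.46, 0.00452). Photosynthesis (5 and 0 of 22, 9 and 0 with total counts, median 0.30, camera adjusted p = 0.00616) and flowering repressors (8 and 2 of 14, 9 and 3 adjusted over the list alone, 0.51, 0.0191) were higher as well. The adjusted p of these 5 was 0.55, 0.574, 0.623, 0.623 and 0.34 with an estimated correlation. Signs differed for mitosis (median 0.08, mean -0.02, tested lower) and the ISWI list (median -0.15, mean 0.04, tested lower), neither called. In all, 4221 genes were higher and 4361 lower, 739 and 1189 by at least 2-fold. The total of 8582 became 5008 without rlt1/2 replicate 1 and 5523 without fha2 replicate 1. Without either of these libraries the called members became 10 higher for auxin, 5 higher for iron deficiency, 3 lower for root hair and 2 higher for photosynthesis, which also had 2 without rlt1/2 replicate 2 and 3 without fha2 replicate 2. Anthocyanin had 4 lower without rlt1/2 replicate 2, 5 without fha2 replicate 1 and 0 higher without any 1 library, the mitosis median was -0.02 without fha2 replicate 1, and aliphatic glucosinolates had 2 lower without rlt1/2 replicate 1 or fha2 replicate 2. List calls ended without rlt1/2 replicate 2 (adjusted p = 0.0735 for aliphatic glucosinolates, 0.215 for anthocyanin) and fha2 replicate 2 (0.0625 for aliphatic glucosinolates), and without overlapping genes for the same lists (0.121 and 0.0625). Under fry they ended for these (adjusted p = 0.158 and 0.1), auxin (0.0806), photosynthesis (0.138), root hair (0.0752) and seed maturation (0.0893).

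The libraries labelled chr11/17 also differed from rlt1/2. JAZ10 was higher by 4.06 ± 0.179 (edgeR, adjusted p = 6.10e-09) and SEP2 (AT3G02310) by 6.42 ± 0.379, LHB1B1 fell by 3.53 ± 0.158 and SAUR20 fell by 4.36 ± 0.224. RLT2 was higher by 3.57 ± 0.145, RLT1 by 1.49 ± 0.165 and CHR11 by 0.52 ± 0.083. FT fell by 1.61 ± 0.374 (edgeR, adjusted p = 0.0026), while FLC (3.97-fold lower by counts, exact interval 0.393 to 196), AGL8 (-0.71 ± 0.361) and AP1 (-0.06 ± 0.704) did not pass. Named extremes were RGF6 (at least 89.7-fold lower, 0.03 on the log2 scale with an overlapping neighbour added), PCC1 (1162-fold lower, exact interval 321 to 9598), SAUR22 (at least 39.4-fold lower) and DPBF2 (AT3G44460) (242-fold lower, interval 43.1 to 9608). On the other side were TIL2 (AT2G27120) (at least 37.3-fold higher), CYP82G1 (518-fold higher, interval 92.5 to 20490), CYP76G1 (AT3G52970) (at least 32.9-fold higher) and BSMT1 (247-fold higher, interval 84.3 to 1203, or 1.37 on the log2 scale with an overlapping neighbour added). Lower lists in the libraries labelled chr11/17 were photosynthesis (22 of 22, median -1.40, camera adjusted p = 5.61e-12), auxin (2 higher and 21 lower of 27, -2.01, 2.02e-05), root hair (0 and 4 of 8, -0.85, 0.0339) and mitosis (2 and 10 of 18, 11 lower adjusted over the list alone, -0.50, 0.0453). Higher lists were jasmonate (18 higher and 0 lower of 21, median 1.38, camera adjusted p = 2.09e-06), anthocyanin (12 and 0 of 15, 1 lower adjusted over the list alone, 0.95, 1.33e-04) and cold and abscisic acid (10 and 1 of 13, 0.76, 0.00434). Shoot meristem (8 and 0 of 8, median 1.01, camera adjusted p = 0.00673) and seed maturation (9 and 0 of 10, 1.68, 0.0121) were higher as well. All 9 had an adjusted p = 0.452 with an estimated correlation. For gibberellin, not called, the median was 0.08, the mean -0.45 and the tested direction lower. In all, 6112 genes were higher and 6274 lower, 1939 and 2602 by at least 2-fold. Calls ended for mitosis without rlt1/2 replicate 1 (adjusted p = 0.1) or chr11/17 replicate 2 (0.0882), for root hair without chr11/17 replicate 2 (0.0882) and for seed maturation without rlt1/2 replicate 1 (0.1). Higher seed maturation genes became 5 without chr11/17 replicate 1, 1 anthocyanin gene was lower without chr11/17 replicate 2, 1 mitosis gene was higher without rlt1/2 replicate 1 or chr11/17 replicate 1, and the gibberellin median was -0.04 without chr11/17 replicate 2.

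Some genes changed in the same direction in all 3 mutants. By the size of their smallest change, the 10 leading ones with a symbol were FLC, BAM5, TCL1, LTI65, AT5MAT, PAP24 (AT4G24890), UGT75C1, JAZ7, GASA6 and DFR. BAM5 was at 27.7 ± 2.02 CPM in Col, 282 ± 8.17 in the libraries labelled chr11/17, 267 ± 25.5 in rlt1/2 and 153 ± 51.0 in fha2. GASA6 was at 543 ± 36.4 CPM in Col and at 4.77 ± 2.24, 38.9 ± 3.42 and 169 ± 35.5 CPM in the mutants in that order. DFR was at 32.0 ± 4.80 against 259 ± 5.82, 139 ± 29.1 and 103 ± 14.7 CPM. In fha2, JAZ7 lost its call without Col replicate 2 (edgeR, adjusted p = 0.0702) or fha2 replicate 2 (0.085), and TCL1 (0.079) and PAP24 (0.0604) without fha2 replicate 2. PAP24, UGT75C1 and GASA6 overlap neighbours, and with both loci added their log2 fold changes in fha2 were -0.61, 0.68 and -1.68.

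**Figure D4:**
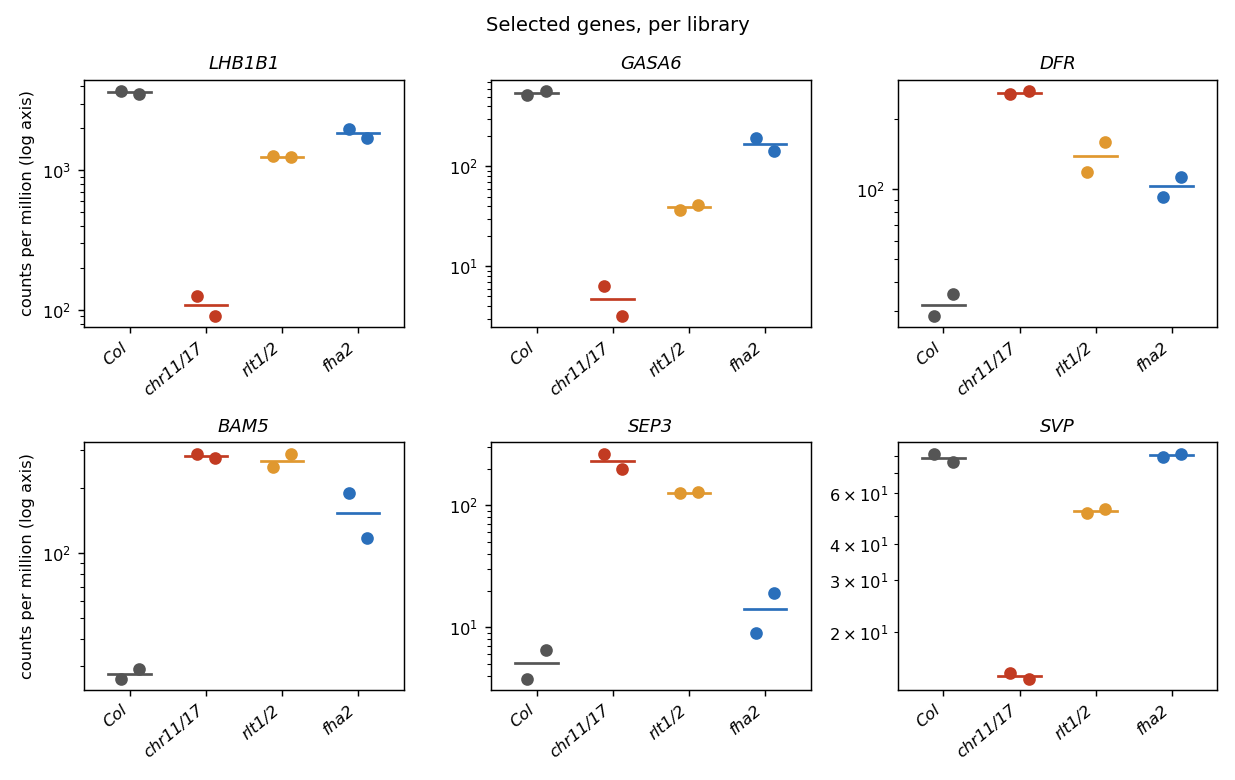
CPM (log axis) of LHB1B1, GASA6, DFR, BAM5, SEP3 and SVP in each library of the 4 genotypes; points are libraries and short lines the means of 2. GASA6 averages 543 CPM in Col and 4.77, 38.9 and 169 CPM in the libraries labelled chr11/17, rlt1/2 and fha2, and SEP3 averages 5.12, 233, 128 and 14.1 CPM in the same order from Col.

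Of the genes changed in both the libraries labelled chr11/17 and rlt1/2, 3138 were higher and 3348 lower in both, where independent lists would share 1360.2 and 1344, and 348 changed in opposite directions. For chr11/17 and fha2, 667 genes were higher and 996 lower in both (459 and 628 for independent lists) and 866 were opposite (1089). For rlt1/2 and fha2, 607 were higher and 914 lower in both (248 and 343) and 246 opposite (590). Of the genes called in fha2, 52.8% were called the same way and 27.5% the opposite way in the libraries labelled chr11/17, 48.3% and 7.8% in rlt1/2, and 459 (14.6%) in neither. In all 3 mutants 505 genes were higher and 802 lower (86.0 and 118 for independent lists). Simulated unchanged groups shared at most 2 called genes. Calls are few by design where no gene changes, so this value is no baseline for the overlaps above. Across the 20866 genes, which are not independent replicates, fold changes had a Pearson's r of 0.718 and a Spearman's rho of 0.691 for chr11/17 and rlt1/2, 0.434 and 0.334 for rlt1/2 and fha2, and 0.263 and 0.162 for chr11/17 and fha2. The shared Col libraries alone give a simulated r of 0.543, 0.536 and 0.537 with no effect. The covariance was 0.969, 0.213 and 0.234 in the same order against simulated values of 0.061, 0.06 and 0.06, so the differences were 0.908, 0.153 and 0.174. With a different single Col library for each mutant of a pair, a split chosen after seeing the data and made in both possible ways, 4968 or 4704 genes changed in the same direction in chr11/17 and rlt1/2 (1979.6 and 1812.8 for independent lists). For chr11/17 and fha2 they were 873 or 723 (537.5 and 408.7), and for rlt1/2 and fha2 707 or 634 (237.7 and 195.9). Opposite calls under the split were 295 or 247, 456 or 311 and 110 or 127. Under the split r was 0.585 or 0.605 for chr11/17 and rlt1/2, 0.159 or 0.189 for chr11/17 and fha2 and 0.233 or 0.247 for rlt1/2 and fha2, with covariances of 0.986 or 1.009, 0.195 or 0.225 and 0.169 or 0.176. Each side of the split holds 1 library, and part of the excess in overlap with all libraries may come from the shared Col libraries. The overlap of chr11/17 and fha2 (1663 genes in the same direction) was 983 without Col replicate 1, 799 without Col replicate 2, 786 without fha2 replicate 1 and 294 without fha2 replicate 2. That of rlt1/2 and fha2 (1521) was 939, 729, 756 and 290, and that of all 3 (1307) was 807, 630, 655 and 250, without the same libraries in that order. With total counts the 3 overlaps were 3548, 3664 and 2910.

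In the authors' deposited table, 5907 genes were higher and 5556 lower at a q-value under 0.05 in the libraries labelled chr11/17, 2500 and 2753 in rlt1/2, and 620 and 1360 in fha2. Across genes, which are not replicates, the authors' log2 fold changes had an r of 0.999, 0.997 and 0.994 with those computed here, and 11377, 5213 and 1818 genes were called in both with the same direction.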

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

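The tests between mutants below were fixed before the results were seen. In 7 cases the median of a gene list lay on opposite sides of 0 in 2 mutants against Col and the camera test between these mutants, on the preset correlation, found a difference; none of the 7 was called with an estimated correlation. No explanation was tested for them.

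Floral organ genes, such as AP3 and SEP3, were lower in fha2 than in the libraries labelled chr11/17 by a median log2 fold change of -3.84 (camera adjusted p = 0.00617, medians against Col -0.28 and 4.44), and lower in fha2 than in rlt1/2 by -2.69 (9.23e-04, medians -0.28 and 2.81). Cold and abscisic acid genes, such as KIN1, were higher in fha2 than in rlt1/2 by 1.01 (camera adjusted p = 0.00348, medians 0.11 and -0.36) and higher in the libraries labelled chr11/17 than in rlt1/2 by 0.76 (0.00434, medians 0.57 and -0.36). Root hair genes were lower in fha2 than in rlt1/2 by -0.87 (camera adjusted p = 0.00764, medians -0.36 and 0.40). They were also lower in the libraries labelled chr11/17 than in rlt1/2 by -0.85 (0.0339, medians -0.73 and 0.40), a call lost without chr11/17 replicate 2. Mitosis genes were lower in the libraries labelled chr11/17 than in rlt1/2 by -0.50 (camera adjusted p = 0.0453, medians -0.30 and 0.35), a call lost without rlt1/2 replicate 1 or chr11/17 replicate 2.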

How the results depend on the processing

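The exceptions listed with the processing, with RLE and total counts as the other scalings, were chosen after seeing the data. The other alternatives were planned. Pseudocounts and an FPKM filter did not apply, since no FPKM value was tested. Of the values that answer a comparison (changed genes, called lists, overlaps, r), 209 kept within the allowed spread under an alternative and 51 moved beyond it. Of single genes, lists and counts per direction, 7485 kept direction and side of the threshold. Calls lost were 327 and gained 18, 26 changed sign and 18 counts moved, cause untested. Most of these genes were picked as called in the same data, which favours keeping a call.

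With total counts 6724 genes changed in fha2 against Col, and the overlaps were 3548 for chr11/17 and fha2, 3664 for rlt1/2 and fha2 and 2910 for all 3 mutants. The r for chr11/17 and rlt1/2 was 0.624 with no filter and 0.772 over genes of at least 10 CPM. With the Col libraries split, 1 to each mutant of a pair, r was 0.585 or 0.605 for chr11/17 and rlt1/2, 0.159 for chr11/17 and fha2 and 0.233 or 0.247 for rlt1/2 and fha2, and overlaps with fha2 were 873 or 723 and 707 or 634 in the same order; fewer libraries entered these tests. With an estimated correlation 0 lists were called by camera in each of the 6 comparisons, and the lists with an unadjusted p under 0.05 were 2 for chr11/17, 3 for rlt1/2 and 2 for fha2 against Col, 2 for fha2 against chr11/17, 2 for fha2 against rlt1/2 and 0 for chr11/17 against rlt1/2. With fry 13 lists were called for fha2 against chr11/17, 6 for fha2 against rlt1/2 and 15 for chr11/17 against rlt1/2.

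Without 1 library, changed genes ranged from 13211 to 13791 for chr11/17 against Col, 5281 to 6387 for rlt1/2, 444 to 1736 for fha2, 13168 to 14210 for fha2 against chr11/17, 5008 to 6723 for fha2 against rlt1/2 and 10081 to 11682 for chr11/17 against rlt1/2. The fewest in fha2 against Col came without fha2 replicate 2. Called lists ranged from 6 to 8, 10 to 14, 4 to 8, 8 to 8, 9 to 11 and 7 to 9 in the same order. The r ranged from 0.655 to 0.737 for chr11/17 and rlt1/2, 0.199 to 0.375 for chr11/17 and fha2 and 0.349 to 0.569 for rlt1/2 and fha2. Overlaps ranged from 4505 to 6748, 294 to 2054 and 290 to 1199 for these pairs and from 250 to 1632 for all 3.

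Libraries of the same number did not deviate together (r from -0.11 to 0.07), so the numbers do not pair them. With the replicate number as a block 14293, 7653, 3045, 14656, 8387 and 12239 genes changed in the 6 comparisons, 8 lists were called in fha2 against Col (5 without the block), r was 0.717, 0.262 and 0.433, and overlaps were 6355, 1584, 1444 and 1240.

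The 26 changes of sign concern genes of the ISWI and flowering lists that were not called. With total counts the log2 fold change became 0.023 for RLT2 and 0.201 for FHA2 in chr11/17, 0.095 for FHA2 in rlt1/2, and in fha2 0.193 for CHR11, 0.235 for RLT1, 0.157 for PTM and 0.123 for AGL8. In fha2 it became 0.006 for RLT1 with limma-voom, and -0.003 for MSI1 with RLE and with DESeq2. Leaving out 1 library gave ranges across 0: against Col, ARID5 from -0.079 to 0.171 and AGL8 from -0.775 to 0.078 in chr11/17, and AGL8 from -0.058 to 0.788 in rlt1/2. In fha2 they were CHR17 from -0.110 to 0.278, RLT1 from -0.233 to 0.255, RLT2 from -0.041 to 0.233, MSI1 from -0.043 to 0.080, FT from -1.285 to 0.512 and AGL8 from -0.479 to 0.366. Between mutants they were RLT3 from -0.308 to 0.105 for fha2 against chr11/17 and from -0.001 to 0.277 for fha2 against rlt1/2, and AP1 from -1.654 to 0.710 for chr11/17 against rlt1/2.

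Depth limits the low genes, as FT and AP1 rest on few counts in Col.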

Other observations

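All product families here, and the tests on Col libraries alone, on root markers, on differences between mutants for the 14 genes changed alike and on the germin-like cluster outside fha2, were chosen only after the results were seen. Ribosomal protein genes were higher in the libraries labelled chr11/17 than in Col (207 higher and 31 lower of 265, median log2 fold change 0.63, camera adjusted p = 1.28e-10, adjusted p = 0.265 with an estimated correlation). In fha2 57 of them were lower (median -0.17, camera adjusted p = 2.90e-08, adjusted p = 0.345 with an estimated correlation), a direction that flips to a median of 0.09 with total counts (43 higher and 14 lower), while the difference from the median of all genes was -0.18 and -0.17 under these scalings. These 57 became 24 without Col replicate 1, 25 without Col replicate 2, 14 without fha2 replicate 1 and 8 without fha2 replicate 2. Histone genes were also higher in the libraries labelled chr11/17 (34 higher and 5 lower of 48, median 1.01, camera adjusted p = 5.00e-07, adjusted p = 0.265 with an estimated correlation). Kinesin genes, motors that include those of cell division, were lower there (3 and 20 of 27, 4 and 13 with total counts, median -0.75, camera adjusted p = 0.00718, adjusted p = 0.265 with an estimated correlation).

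Peroxidase genes were higher in rlt1/2 (34 higher and 0 lower of 66, 23 and 4 without Col replicate 2, 34 and 1 without Col replicate 1 and 28 and 1 without rlt1/2 replicate 2, median 0.60, camera adjusted p = 7.52e-07, adjusted p = 0.325 with an estimated correlation). Glutathione transferase genes were higher in rlt1/2 (23 and 2 of 42, median 0.62, camera adjusted p = 1.01e-05) and in the libraries labelled chr11/17 (23 and 7, median 0.92, 0.00291), with an adjusted p of 0.325 and 0.265 with an estimated correlation. The SAUR family, small auxin-induced genes, was lower in all 3 mutants. It had 34 lower and 12 higher of 62 in the libraries labelled chr11/17 (median -0.94, camera adjusted p = 0.00898), 27 and 7 in rlt1/2 (-0.49, 0.00641) and 18 and 4 in fha2 (-0.67, 2.67e-06). With an estimated correlation the adjusted p was 0.265, 0.325 and 0.345, and with total counts the medians were -0.66, -0.21 and -0.42 and the lower and higher members 33 and 14, 24 and 15, and 14 and 8. The 18 in fha2 became 7 without fha2 replicate 2, and the 4 higher ones 0 without any 1 of the 4 libraries of Col and fha2. Immune receptor genes with TIR and NBS domains were lower in the libraries labelled chr11/17 (6 higher and 43 lower of 74, median -0.57, camera adjusted p = 6.15e-04, adjusted p = 0.114 with an estimated correlation). Each other median given for these families kept its sign with RLE size factors and with total counts.

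Photosynthesis genes were lower in every mutant against Col. In the libraries labelled chr11/17 the list was also lower than in rlt1/2 (median -1.40, 22 of 22 genes). In fha2 it was higher than there (1.62, 22 of 22). These values argue against the Col libraries alone as the cause there. For rlt1/2 or fha2 a property of the Col libraries cannot be told apart from an effect of the genotype. There is no second Col set, and the median of 0.30 in fha2 against rlt1/2 leaves the step from Col open. TMM factors do not give the fall in fha2 (median -0.37 with total counts). Abundant genes as a cause stay open, as the list is among them. A smaller share of green tissue against root cannot be told apart in any mutant: root markers had medians of -0.46 in the libraries labelled chr11/17 (2 higher and 3 lower of 11, 0.04 without chr11/17 replicate 1), 0.15 in rlt1/2 (2 higher and 1 lower) and -0.10 in fha2 (0.14 with total counts), and root hair genes of -0.73, 0.40 and -0.36. A role of the ISWI subunits in the level of these transcripts, the difference named by the design, stays open as an untested hypothesis.

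In all 3 mutants 14 genes, among them MYC2, CSLG2 and CYP78A5, changed in the same direction by a fitted log2 fold change of at least 3 in size, with at most 13 counts per library on the lower side. Of these 5 overlap another listed gene (35.7%, against 27.3% of genes tested, Fisher's exact test, two-sided, p = 0.549), and an exchange of reads between overlapping genes cannot be told apart from a change of the genes themselves, since adding the counts of a more abundant neighbour shrinks either. Of the 14 genes, 8 were called between the libraries labelled chr11/17 and rlt1/2, but so were 12386 of the 20866 genes tested. A call between these mutants is thus common, and it leaves the step from Col open. A difference of the Col plants alone cannot be told apart from an effect of the genotype for any of the 14. There is no second set of Col libraries. The 8-gene cluster of the germin-like genes AT5G39150 and AT5G39180 was at 19.2 and 16.9 summed CPM in Col. Its log2 change was -2.2 in the libraries labelled chr11/17 (2.13 and 5.70). It was -0.92 in rlt1/2 (9.07 and 9.93) and -1.17 in fha2 (7.68 and 8.38). A shift of reads among near-identical copies does not give this lower sum. Whether it adds to the larger falls of these genes is open. An effect of the genotypes on these loci stays open and was not tested.

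A block of 45 genes on chromosome 2 that resemble the mitochondrial genome had 14 members lower and 0 higher in fha2 (median -1.0, -0.75 with total counts; 9 lower without Col replicate 2 and 6 without fha2 replicate 2), 9 and 0 in rlt1/2 (median -0.38, -0.10 with total counts, from -0.71 without rlt1/2 replicate 1 to -0.15 without rlt1/2 replicate 2; 6 and 0 without Col replicate 2 or rlt1/2 replicate 1, and 5 and 2 without rlt1/2 replicate 2) and 8 and 5 in the libraries labelled chr11/17 (median -0.13, 0.14 with total counts, from -0.25 without Col replicate 1 to 0.05 without Col replicate 2; 5 and 9 with total counts, 5 lower without Col replicate 1, Col replicate 2 or chr11/17 replicate 2 and 4 without chr11/17 replicate 1). Reads of the mitochondrial genome counted on nuclear copies may account for the fall in fha2, but outside the block 1 such gene was tested (-1.72), so this cannot be told apart from a change of the nuclear copies. A change of the surrounding region does not account for it in fha2, since the nearest 40 genes, 20 on each side, had a median of 0.04 (quartiles -0.17 and 0.22). A test on genes inside the block that do not resemble the mitochondrial genome had been planned and was void, as the block holds none that was tested, and the test on its flanks took its place. An effect of the genotypes on the nuclear copies stays open and was not tested.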
